A study of Mus musculus with 6 samples.

How the data were processed

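RNA from intestine (jejunum and ileum) of 8-week-old male mice was sequenced in 6 libraries, 3 from wild-type (WT) mice and 3 from mice that lack SHP (SHP-KO). SHP, the small heterodimer partner, is an orphan nuclear receptor encoded by Nr0b2 that acts as a transcriptional corepressor. Food was withheld overnight and then given back for 6 h before sampling. Libraries were read on an Illumina HiSeq2000 as 100 bp reads, per the labels' protocols.

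The submitters' processing notes name bcl2fastq 2.17.1.14, Trimmomatic 0.38, FastQC 0.11.5 and STAR 2.6.0c, with mm9 as the genome build, and the settings of these tools are not given in the sources used here. The deposited values per library are whole-number counts of reads per gene, made with featureCounts 1.5.2 per the file headers. The counting was unstranded and summed over exons of each gene, per the file headers, so that reads of overlapping or antisense genes cannot be told apart. Reads with several alignments were not counted under those settings, which lowers the counts of genes with close copies, such as the alpha-defensins. The authors' deposited comparison table holds log2 fold changes and log2 mean CPM, with p-values and adjusted p-values, and the submitters' processing notes name edgeR without a version. An edgeR exact test with an assumed biological coefficient of variation (CV) of 0.2, on genes above 1 CPM in at least 1 library, gave the same 12939 genes, and its log2 fold changes and p-values differed from the table's by at most 5.3e-15 and 6.0e-15.

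The total count was 13511800, 11265437 and 13089989 in WT replicates 1 to 3 and 7956528, 9289543 and 8862048 in SHP-KO replicates 1 to 3. These totals set the precision of low values, and intervals and floors given here cover counting error only, because reads were counted without molecular identifiers. Of 23284 genes in the files, 12106 passed edgeR's filterByExpr with its minimum count of 10 and were tested.

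Counts were scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 (robust fit) in R 4.3.3. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05. Standard errors (SE) of log2 fold changes were derived from that fit. CPM values are TMM-scaled, given as mean ± SD over 3 libraries. A fold change against a group with no counts is a lower bound, computed with a floor of 3 counts over the group, and with 1 to 3 counts the ratio of summed counts is given with its exact 95% interval. The labels do not say whether the libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

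Before the data were examined, 38 gene lists were fixed (pathways, intestinal segments and markers of cell types that the tissue could hold), and 36 with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01. Camera asks whether a list's genes moved relative to all other genes. Named genes followed a rule fixed at the same time: Nr0b2 and Npc1l1; the 8 largest rises and 8 largest falls among genes with an adjusted p under 0.05, no overlap of the groups' CPM and a mean of at least 1 CPM; up to 3 genes per list with the smallest p; and Abcg5, Abcg8, Scarb1, Soat2, Srebf2, Fgf15, Slc10a2, Fabp6, Mttp and Apob. Some genes that the rule takes are not reported here. Other list members are named only where they go against their list, or were picked after their values were seen, as are Cd36, Gata4, Lss, Abca1, Pcsk1 and the genes named for their scatter between libraries. Counts within a list adjusted over the list alone equalled those adjusted over all tested genes in every list.

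On simulated counts of 12106 genes, with 50 genes changed at each of 4 sizes (drawn from genes of at least 60 counts), the test recovered 26 genes at 1.25-fold, 38 at 1.5-fold, 47 at 2-fold and 50 at 4-fold, with 5 false calls among 11677 unchanged genes that were tested, another 229 being removed by the filter. The simulation changed 200 genes, whereas 8543 were called in the data, so these rates need not hold for the real comparison. Alternatives fixed beforehand were DESeq2 size factors, no scaling factors, other filters, DESeq2 1.42.0, limma-voom, a fit without robust estimation, the replicate number as a block, leaving out each library, an estimated correlation and fry for lists, and other windows around Nr0b2. The exact tests, with an assumed CV of 0.2 and with the estimated common CV, were added after the data were seen. Figures were drawn with matplotlib 3.10.9. Coordinates are those of the count files, in mm9, and a reference of another build was not used.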

Results

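Intestinal RNA of refed WT and SHP-KO mice was compared to ask which transcripts differ when SHP is absent, with cholesterol uptake through Npc1l1 as the focus named in the study's title. Each genotype had 3 libraries, with total counts between 7956528 and 13511800. Libraries of a genotype correlated across genes at r = 0.990 to 0.994 and libraries of different genotypes at 0.922 to 0.924, values over genes, which are not independent replicates. The first principal component held 87.0% of the variance and separated the genotypes.

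Nr0b2, the gene that encodes SHP, was nearly absent from SHP-KO libraries. It lies on chromosome 4 from 133109305 to 133112451 (mm9) with 2 exons. WT libraries held 31, 14 and 23 counts, or 1.74 ± 0.52 CPM (SD, n = 3), and SHP-KO libraries held 1, 0 and 0, so that without replicate 1 none is left. The summed counts of 68 and 1 give a ratio of 45.6, with a 95% counting interval of 7.92 to 1829, and the adjusted p was 4.5e-10 in edgeR's quasi-likelihood test. Nr0b2 was thus a low-count transcript in WT tissue too, and no log2 value is given for it beyond this ratio.

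Npc1l1, the transporter through which enterocytes take up dietary and biliary cholesterol, was 2.04-fold higher in SHP-KO. Its level was 1737 ± 8.81 CPM in WT and 3548 ± 100.3 CPM in SHP-KO (SD, n = 3), a log2 fold change of 1.03 (SE 0.023, adjusted p 5.7e-58, edgeR). The gene spans 6111014 to 6130248 on chromosome 11 (mm9), with 19 exon intervals. Without any 1 of the 6 libraries the log2 fold change stayed between 1.01 and 1.04. In the same libraries 11 of 12 tested members of the fixed proximal small intestine list rose, with a median log2 fold change of 1.28. The labels give no share of jejunum and ileum, so for Npc1l1 a difference in that share cannot be told apart from SHP loss.

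Genes that handle sterols around Npc1l1 moved both ways. Soat2, which esterifies absorbed cholesterol, rose from 196.7 ± 5.84 to 401.7 ± 7.11 CPM (log2 1.03). Abcg5 rose (log2 0.59, SE 0.028), whereas Abcg8, its partner in the heterodimer that pumps sterols back into the lumen, fell (log2 -0.33, SE 0.032). The fall of Abcg8 did not pass with the assumed CV of 0.2, chosen after seeing the data (adjusted p 0.30, edgeR exact test). Abca1, which exports cholesterol to lipoproteins, was higher at log2 1.17 (SE 0.28, adjusted p 0.018, edgeR). Its SHP-KO libraries were far apart, at 49.0, 76.3 and 42.3 CPM in replicates 1 to 3. Scarb1, a lipoprotein receptor, was near the floor of detection, with 24 counts in all WT and 37 in all SHP-KO libraries. Its rise (log2 1.18, adjusted p 0.0056, edgeR) was lost without WT replicate 3 (adjusted p 0.057) or without SHP-KO replicate 1 (adjusted p 0.062). Of 20 tested members of the sterol absorption and efflux list, 11 rose, 6 fell and 3 did not pass, and the list as a whole was not called (camera adjusted p 0.14).

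Cholesterol synthesis genes likewise moved apart. Srebf2, which encodes the transcription factor that drives the pathway, rose from 165.8 ± 3.90 to 477.3 ± 41.7 CPM (log2 1.53). Sqle, an early enzyme of the sterol branch, rose by log2 1.89. In contrast Sc4mol fell from 322.8 ± 3.32 to 71.1 ± 1.19 CPM and Lss had a log2 fold change of -2.17. Of 24 tested members, 9 rose, 7 fell and 8 did not pass, and camera called no shift of the list (adjusted p 0.47).

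**Figure D1:**
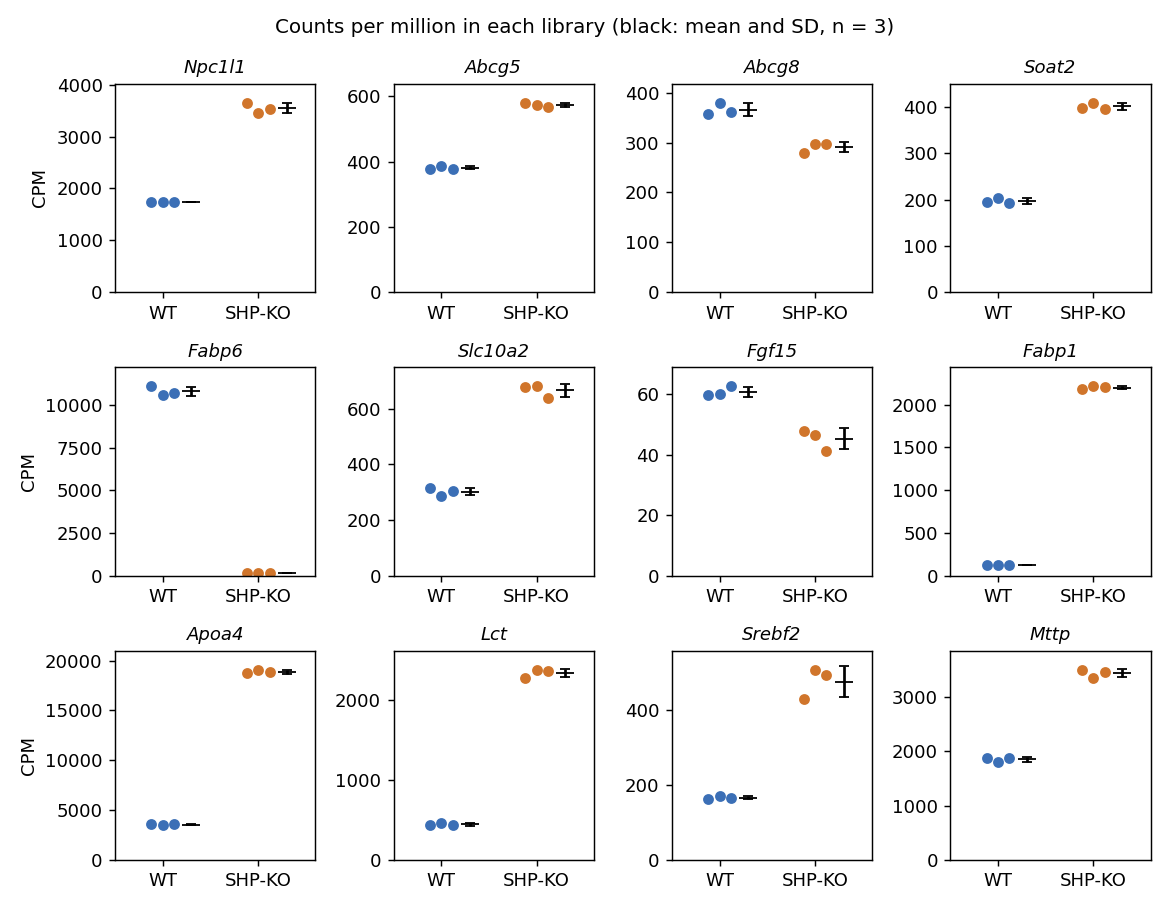
CPM (vertical axes, from 0) of 12 genes in each WT and SHP-KO library (points), with the mean and SD of 3 libraries in black. Fabp6 goes from 10792 to 144.5 CPM and Npc1l1 from 1737 to 3548 CPM, and no library of one genotype overlaps the other in any panel.

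Bile acid handling was mostly lower in SHP-KO. Fabp6, the cytosolic bile acid carrier of the ileum, fell 74.7-fold, from 10792 ± 251.9 to 144.5 ± 4.67 CPM. Osta and Ostb, which together export bile acids across the basolateral membrane, fell by 1.51 and 1.61 on the log2 scale, and Nr1h4, the bile acid receptor FXR, fell by 1.90. Slc10a2, the apical bile acid importer, was the exception and rose from 302.8 ± 13.3 to 666.0 ± 23.5 CPM (2.20-fold). Fgf15, the hormone that FXR induces in ileum, was at 60.9 ± 1.59 CPM in WT and 45.3 ± 3.46 in SHP-KO (log2 -0.43), a call that was lost with the assumed CV of 0.2 (adjusted p 0.17, edgeR exact test). In this list 9 of 13 members fell, 1 rose and 3 did not pass (camera adjusted p 1.7e-13, and 0.013 with an estimated correlation). Fabp6, Osta, Ostb, Slc10a2 and Fgf15 also stand in the fixed ileum list, of which 12 of 18 markers fell in these libraries.

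Genes of fat absorption and chylomicron assembly were mostly higher. Apoa4, an apolipoprotein of chylomicrons, rose from 3525 ± 59.8 to 18859 ± 160.2 CPM. Fabp1 rose 17.3-fold, Apoc2 9.70-fold, and Cd36, a fatty acid transporter, went from a mean of 3.51 to 47.8 CPM (log2 3.77). Mttp, which loads lipid onto nascent chylomicrons, rose by log2 0.89, whereas Apob was at 3831 ± 84.4 CPM in WT and 3713 ± 23.0 in SHP-KO and did not pass (adjusted p 0.061, edgeR). Apob passed in several other settings at log2 values down to -0.11. Of 27 members 17 rose, 4 fell (Acsl3, Sar1b, Lpin2 and Apoa1) and 6 did not pass (camera adjusted p 3.0e-24, and 0.013 with an estimated correlation). Fabp1 and Apoa4 also stand in other fixed lists, as proximal or enterocyte markers. All 10 adipocyte and all 17 smooth muscle markers tested rose in the same libraries.

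Markers of the upper small intestine were higher and markers of ileum mostly lower. Lct, the brush border lactase, rose 5.30-fold, Gip, the hormone of K cells, 8.13-fold, and Gata4, a transcription factor that marks jejunum, had a log2 fold change of 1.05. Of 12 proximal markers 11 rose and 1, Slc40a1, fell (camera adjusted p 1.8e-21, and 0.013 with an estimated correlation). Tmigd1 fell from 2793 ± 37.2 to 494.4 ± 7.71 CPM. Among 18 ileum markers 12 fell and 6 rose, those 6 including Slc10a2, Pyy and Enpp3 (camera adjusted p 6.3e-11, and 0.017 with an estimated correlation). Labels give the tissue only as jejunum and ileum together.

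Markers of the muscle wall and its nerves were higher in SHP-KO in the same libraries. All 17 smooth muscle markers rose, with a median log2 fold change of 2.14, among them Acta2 from 27.9 ± 2.16 to 225.7 ± 7.67 CPM, Flna and Des (camera adjusted p 2.8e-28, and 0.013 with an estimated correlation). Of 14 markers of enteric neurons and glia 13 rose and Ret fell, with Hand2, Prph and Tubb3 at log2 2.80, 2.05 and 2.87 (camera adjusted p 0.0083, but adjusted p 0.24 with an estimated correlation). All 10 adipocyte markers rose, Fabp4 by log2 2.92 and Car3 by log2 4.69 (camera adjusted p 0.0028, but adjusted p 0.083 with an estimated correlation). Car3 had 5, 1 and 2 counts in WT, and without WT replicate 1 its log2 fold change was 5.40. Of 17 fibroblast and matrix genes 15 rose and 2, Bgn and Dcn, did not pass, with Col3a1 at log2 2.12 and Col6a1 at log2 2.47 (camera adjusted p 0.00030, but adjusted p 0.11 with an estimated correlation).

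B cell genes were almost absent from SHP-KO libraries. Faim3, an IgM receptor, was at 8.86 ± 0.97 CPM in WT with no count in SHP-KO, at least 76.1-fold lower, and Cr2, a complement receptor of follicular B cells, was at least 44.1-fold lower. Ms4a1, which encodes CD20, had 286 counts in WT and 1 in SHP-KO, a ratio of 192 (95% counting interval 34.2 to 7609), and without SHP-KO replicate 3 it had no count in SHP-KO. Cd79a and Cd79b, the signalling chains of the B cell receptor, fell by 5.30 and 5.27 on the log2 scale. Igj, the joining chain made by plasma cells, rose from 34.5 ± 1.02 to 100.1 ± 7.13 CPM. In the list 15 of 17 members fell, Igj rose and Derl3 did not pass, with a median log2 fold change of -5.21, which was the same with 2 members of 0 counts set at their bound (camera adjusted p 7.2e-06, but adjusted p 0.11 with an estimated correlation).

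Goblet and enteroendocrine cell markers were mostly higher. Goblet cell genes Zg16, Fcgbp and Tff3 rose 3.04-fold, 2.9-fold and 2.9-fold, and 12 of 14 goblet markers rose while Ccl9 and Guca2a fell (camera adjusted p 5.5e-14, and 0.013 with an estimated correlation). Of 18 enteroendocrine markers 16 rose, 1 (Gcg) fell and 1 (Pcsk1) did not pass (camera adjusted p 1.6e-06, and 0.034 with an estimated correlation), with Chga and Chgb at log2 1.68 and 2.13. Enterocyte markers went both ways, 11 higher, 6 lower and 2 not passing, with Rbp2, a retinol carrier, up 3.82-fold (camera adjusted p 2.7e-06, and 0.034 with an estimated correlation). Paneth cell genes, whose alpha-defensins have close copies and uncertain counts, gave 11 lower, 3 higher and 5 not passing of 19 (camera adjusted p 0.13), with Defa22 and Defa20 at log2 -1.49 and -1.04. Smooth muscle, nerve and fat markers rose in these libraries as well.

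Genes of dividing cells were lower. Top2a fell from 19.3 ± 1.28 to 3.81 ± 0.14 CPM, Hmgb2 3.26-fold and Mcm6 2.31-fold. Of 30 cell cycle genes 27 fell, Plk1 and Mcm2 rose and Kif20a did not pass (camera adjusted p 4.7e-05, but adjusted p 0.060 with an estimated correlation). The 14 intestinal stem cell genes gave 8 lower, 3 higher (Hopx, Smoc2 and Lgr5) and 3 not passing, with Olfm4, Prom1 and Axin2 at log2 -1.62, -0.73 and -0.56 (camera adjusted p 0.38). Axin2 did not pass with the assumed CV of 0.2 (adjusted p 0.061, edgeR exact test). B cell markers fell and smooth muscle markers rose in these libraries as well.

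**Figure D2:**
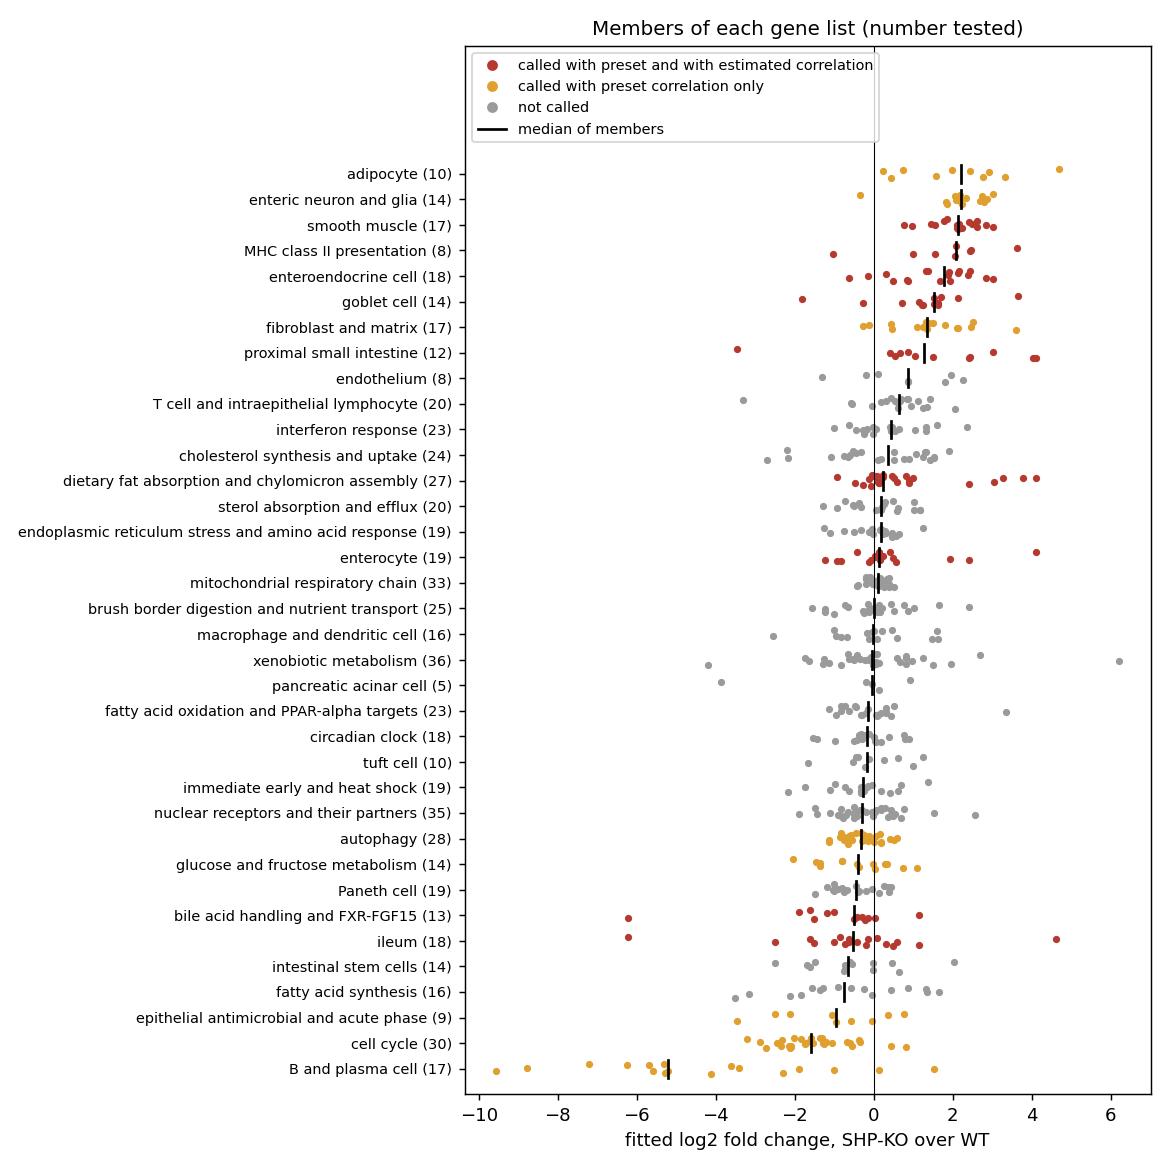
Fitted log2 fold change of SHP-KO over WT (horizontal axis) for tested members (points) of 36 gene lists (rows, number tested in brackets), with the median of each list in black and colours for the camera call. B and plasma cell markers have the lowest median, -5.21, and adipocyte markers the highest, 2.22; 2 members with no SHP-KO counts are drawn at their fitted values, which are not bounds.

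MHC class II genes, which present antigen to helper T cells, were higher. Cd74 rose from 213.3 ± 3.23 to 1171 ± 16.2 CPM, H2-Ab1 5.38-fold and H2-Aa 4.26-fold. In that list 7 of 8 members rose and Ctss, a lysosomal protease, fell (camera adjusted p 1.5e-23, and 0.013 with an estimated correlation). In the same libraries 15 of 17 B and plasma cell markers fell, and 17 of 17 smooth muscle, 15 of 17 fibroblast and matrix and 10 of 10 adipocyte markers rose. Epithelial antimicrobial genes were mostly lower, with Reg3g, Nos2 and Reg3b at log2 -2.12, -2.50 and -0.58. There 6 of 9 fell, Reg3a and Reg4 rose and Duox2 did not pass (camera adjusted p 0.00041, but adjusted p 0.10 with an estimated correlation). Of 23 interferon response genes 13 rose, 5 fell and 5 did not pass (camera adjusted p 0.14), with Isg15, Stat2 and Irf1 at log2 1.33, 1.05 and 0.63. T cell markers gave 12 higher, 1 lower (Cd2) and 7 not passing of 20 (camera adjusted p 0.31), among them Cd8a, Gzma and Ccl5 at log2 1.24, 0.68 and 0.85. The 16 macrophage and dendritic cell markers gave 4 higher, 5 lower and 7 not passing (camera adjusted p 0.66), with Lyz2 at log2 -2.56, Itgam at 1.63 and Cd68 at 1.48.

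Genes of the glucose and fructose list mostly fell. Pck1, which encodes the cytosolic PEP carboxykinase, went from 1713 ± 9.91 to 415.3 ± 6.92 CPM, and Fbp1 and Txnip fell by 1.45 and 1.37 on the log2 scale. In that list 8 of 14 members fell, 4 rose (Slc37a4, Khk, Ppargc1a and Pfkfb3) and 2 did not pass (camera adjusted p 0.00077, but adjusted p 0.060 with an estimated correlation). Autophagy genes were lower in 19 of 28, higher in 4 (Gabarap, Atg2a, Optn and Atg16l1) and not passing in 5, with the cargo receptors Sqstm1 and Nbr1 2.21-fold and 1.58-fold lower and Wipi2 1.69-fold lower (camera adjusted p 0.038, but adjusted p 0.13 with an estimated correlation). Cell type markers moved in these libraries as well: 17 of 17 smooth muscle and 10 of 10 adipocyte markers rose, and 15 of 17 B and plasma cell markers fell.

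The remaining metabolic lists were not called. Fatty acid synthesis gave 9 lower, 5 higher and 2 not passing of 16 (camera adjusted p 0.11): Scd2, a desaturase, fell 11.3-fold, while Acly and Mlxipl rose by log2 1.66 and 1.34. Fatty acid oxidation and PPAR-alpha targets gave 10 lower, 10 higher and 3 not passing of 23 (adjusted p 0.53), with Angptl4 at log2 -1.13, Cpt1a at -0.72 and Acaa2 at 0.53, the last not passing with the assumed CV of 0.2 (adjusted p 0.076, edgeR exact test). Xenobiotic genes gave 14 higher, 16 lower and 6 not passing of 36 (adjusted p 0.72), with a positive mean (0.075) beside a negative median (-0.038). Cyp3a11 and Cyp2b10 rose 2.38-fold and 3.90-fold and Ces2a fell 3.31-fold (log2 -1.73). Cyp2c29, with 2 counts in WT and 122 in SHP-KO, had a ratio of 90.9 (95% counting interval 24.6 to 759). Brush border genes gave 12 higher, 12 lower and 1 not passing of 25 (adjusted p 0.72), with the peptidases Ace at log2 1.66 and Mep1a at -1.56. Respiratory chain genes gave 19 higher, 6 lower and 8 not passing of 33 (adjusted p 0.39), none of which passed with the assumed CV of 0.2, including Ndufa2, Uqcrc2 and Atp5c1 at log2 0.53, -0.42 and -0.39.

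Regulatory lists were not called either. Among 35 nuclear receptors and partners 12 rose, 19 fell and 4 did not pass (camera adjusted p 0.44): Nr1i3, the xenobiotic receptor CAR, rose 5.87-fold. Clock genes gave 5 higher, 10 lower and 3 not passing of 18 (adjusted p 0.72), with Nr1d1 at log2 0.76 and Per2 at 0.90. Endoplasmic reticulum stress genes gave 10 higher, 4 lower and 5 not passing of 19 (adjusted p 0.72), with Ddit3 2.38-fold higher, Herpud1 at log2 -1.10 and Atf4 at 0.48, the last not passing with the assumed CV of 0.2 (adjusted p 0.11, edgeR exact test). Immediate early and heat shock genes gave 4 higher, 9 lower and 6 not passing of 19 (adjusted p 0.20), with Fos, Atf3 and Btg2 at log2 -0.97, -1.74 and -1.10. Endothelial markers gave 5 higher, 1 lower (Tie1) and 2 not passing of 8 (adjusted p 0.65), with Esam and Eng at log2 2.27 and 1.81. Tuft cell markers gave 3 higher, 3 lower and 4 not passing of 10 (adjusted p 0.86), with a negative median beside a positive direction of the test, and Trpm5, Ltc4s and Rgs13 at log2 1.24, 0.99 and -1.65. Of 5 pancreatic acinar genes Gp2 fell 14.5-fold, Klk1 rose by log2 0.91 and 3 did not pass (adjusted p 0.52). No erythrocyte marker passed the count filter, and the 1 tested mast cell gene, Kit, had 160 counts in WT and 88 in SHP-KO and did not pass (log2 -0.29, adjusted p 0.22, edgeR).

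Beyond the lists, the largest rises included Igfbp2, with no counts in WT and at least 27.3-fold higher in SHP-KO, and Csf2, the cytokine GM-CSF, at 0.23 ± 0.065 CPM in WT and 6.41 ± 0.045 in SHP-KO. BC002163 rose from 1.20 ± 0.052 to 36.9 ± 1.89 CPM and Ano3 by log2 5.17 from 7 counts in WT. Tcp10a, Tshz3 and Ppm1n, with 2 or 3 counts in WT, had count ratios of 39.5 (95% counting interval 10.4 to 334), 34.8 (11.4 to 173) and 31.3 (10.2 to 156). Without WT replicate 3 the fitted log2 fold changes of Tshz3 and Ppm1n went from 4.92 to 5.70 and from 4.77 to 5.55. The largest falls, besides Fabp6, Faim3, Cr2 and Ms4a1, were Fcer2a (at least 40.3-fold lower), Cxcl13 (count ratio 110.5, 95% counting interval 37.6 to 538), Tnfrsf13c (count ratio 87.3, 23.9 to 724) and the metallothionein Mt2, from 50.4 ± 2.89 to 0.80 ± 0.60 CPM. Without SHP-KO replicate 2 the fitted log2 fold change of Cxcl13 went from -6.65 to -7.49.

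In all, 8543 of 12106 genes differed between the genotypes (70.6%), 4260 higher and 4283 lower in SHP-KO, of which 2425 changed by at least 2-fold and 773 by at least 4-fold. With an exact test and a CV of 0.2 assumed in place of the estimated spread, a setting added after the data were seen, 4041 genes passed, 2164 higher and 1877 lower. Camera called 17 of 36 lists, 10 higher and 7 lower, and 9 of them with an estimated correlation. The common biological CV estimated from the libraries was 2.97%, and pairs of libraries of a genotype had a mean chi-square of 1.33 to 1.97 per gene where counting noise alone gives about 1, against 88.3 to 103.3 between genotypes.

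A small group of genes was far apart between libraries of SHP-KO, singled out after the values were seen. Of 8877 genes with at least 50 counts in that genotype, 6 differed over 3-fold between the highest and the lowest library: Mvd (9.16, 53.8 and 166.0 CPM in replicates 1 to 3), Pmvk (125.1, 12.9 and 12.8), Prkaa2 (16.3, 15.5 and 115.3), Tm7sf2 (136.7, 73.6 and 18.6), Hsd17b7 (30.8, 130.9 and 92.5) and Nsdhl (54.9, 14.3 and 49.6). All but Prkaa2 belong to the cholesterol synthesis list. Of 5680 genes with at least 20 CPM, 16 differed at least 1.5-fold, and 11 of those are among the 22 list members at that level (Fisher's exact test, two-sided, p 6.2e-25, over genes, which are not independent). In WT, Abcc3 alone differed over 3-fold (18.3, 56.5 and 22.5 CPM). None of these 7 genes was called between the genotypes in the main edgeR fit, but without its robust estimation Mvd, Prkaa2, Tm7sf2, Hsd17b7 and Nsdhl passed (adjusted p up to 0.045).

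**Figure D3:**
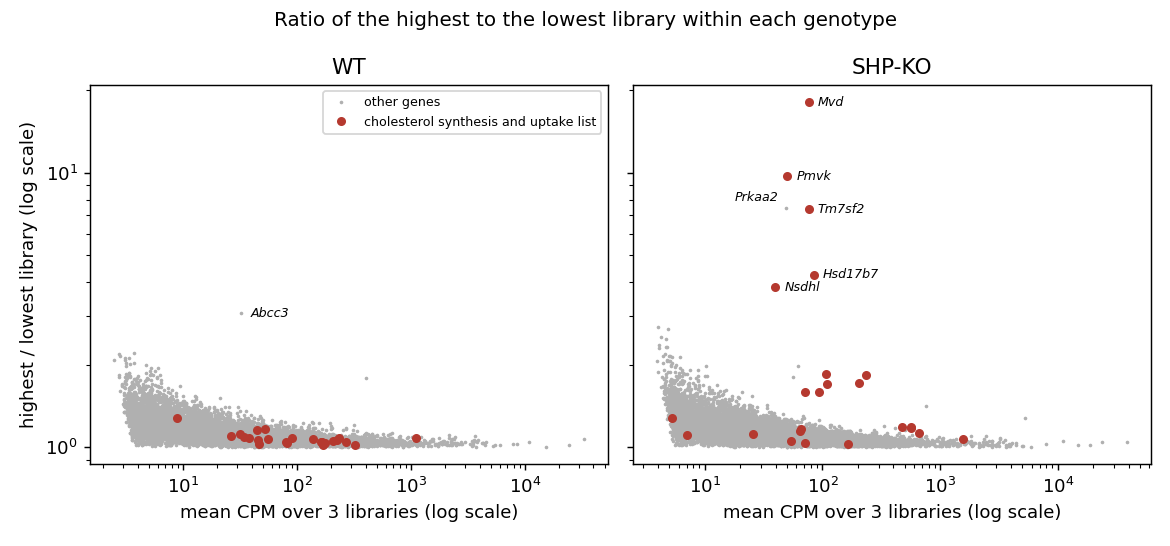
Ratio of the highest to the lowest of 3 libraries (vertical, log scale) against mean CPM (horizontal, log scale) for each gene with at least 50 counts, in WT (left) and SHP-KO (right), with the cholesterol synthesis and uptake list in red. In SHP-KO 5 list members lie above 3 and Mvd reaches 18.1, while in WT no list member does.

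Genes near Nr0b2 were examined because a knockout can carry flanking sequence of another strain. Within 10 Mb of Nr0b2 192 of 243 tested genes were called (79.0%), against 70.4% of the others (odds ratio 1.58, Fisher's exact test, two-sided, p 0.0035). For changes of at least 2-fold the shares were 19.8% and 20.02% (p 1.0), and with a 20 Mb window the odds ratio was 1.19 (p 0.13).

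The authors' deposited table called 4483 of its 12939 genes at an adjusted p of 0.05, 2460 higher and 2023 lower in SHP-KO. Of these, 4051 were called here as well and 5 of the genes tested here were called in the authors' deposited table only, while 4492 were called here only.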

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

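The exact tests and the 2-fold limit near Nr0b2 were added after the data were seen. The counts of changed genes stayed within 1.5 times under each alternative planned beforehand, from 7528 (DESeq2 Wald test) to 9452 (no filter on low counts), and Npc1l1 kept its direction and call in all. The edgeR exact test with an assumed CV of 0.2 passed 4041 genes, 2164 higher and 1877 lower, and the same test with the estimated common CV of 2.97% passed 8587, so that the drop goes with the CV and not with the test. Of the 17 lists called, 9 passed with an estimated correlation. Among the lists lost, that estimate was below the preset 0.01 for adipocyte (-0.046), glucose and fructose (-0.035) and autophagy (-0.033). A higher correlation is therefore not what removed these calls, whereas the estimate was above 0.01 for the other lists lost. Fry, which tests whether a list's genes move one way and does not compare them with other genes, called 33 lists. The odds ratio near Nr0b2 was 1.64 with a 5 Mb window (p 0.015) and 1.19 with 20 Mb (p 0.13); the cause was not tested. Without single libraries 8260 to 8407 genes passed and 17 lists were called each time. Mvd then ranged from -0.47 to 1.27, Pmvk from -1.80 to 0.59, Prkaa2 from -0.95 to 1.12, Tm7sf2 from -0.18 to 0.98 and Abcc3 from -0.53 to 0.40 (log2), as these genes differ between libraries of a genotype; tests on the cholesterol synthesis genes among them left the cause open, and the cause for Prkaa2 and Abcc3 was not tested. Pmvk (0.12) also turned to -0.78 with limma-voom and to -0.21 with the replicate block. Of genes not called in the main fit, Pmvk (adjusted p 5.0e-31) and Prkaa2 (4.7e-13) passed as lower and Hsd17b7 (0.0086) as higher without 1 SHP-KO library, Abcc3 (4.0e-05) as higher without WT replicate 2, and Pmvk, Hsd17b7 and Nsdhl passed with limma-voom. Abcg2 (log2 -1.28) did not pass without any 1 SHP-KO library (adjusted p up to 0.072, edgeR), but passed with each WT library left out in turn. Its spread lies in WT, at 320.7, 565.3 and 316.6 CPM in replicates 1 to 3, against 162.9, 167.3 and 160.8 in SHP-KO. Of 133 named genes, 115 kept their direction and call in every setting. Whether the replicate numbers pair the libraries cannot be read from their deviations, because libraries of a genotype differ by little more than counting noise. Deviations of same-numbered libraries correlated at 0.016, 0.017 and -0.0066, and those of other pairs at -0.024 to 0.0091. With the replicate block 8573 genes and 17 lists were called. Counts limit low genes: in the simulation 13 of the 25 genes with the lower counts were recovered at 1.5-fold and 25 of the 25 with the higher, and at 2-fold 22 and 25.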

Other observations

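Of the tests here, those on the ileum, jejunum, wall, repeat-library and cholesterol explanations were chosen after the values were seen, and so was the percentile beside each unseen gene set; the splits of the libraries, the unseen follicle genes and the unseen glucocorticoid genes were chosen before theirs. Genes that glucocorticoids induce in many tissues were low in SHP-KO, an observation made after the values were seen on genes in the fixed lists (Pck1, Per1, Dusp1 and Angptl4) and outside them. Fkbp5 went from 179.0 ± 8.09 to 6.13 ± 0.86 CPM (SD, n = 3), Sgk1 from 1208 ± 28.7 to 139.9 ± 6.43 CPM and Tsc22d3 from 290.4 ± 5.26 to 93.6 ± 6.53 CPM. All 9 such genes whose values had been seen were lower. A hypothesis is that glucocorticoid signalling was lower in the SHP-KO tissue when it was taken, and it was tested on 13 further responsive genes whose values had not been looked at. Their median log2 fold change was -0.55, lower than all but 0.53% of 10000 random lists matched on expression, with 8 lower, 4 higher (Arl4d, Scnn1a, Slc9a3 and Sdpr) and Lpin1 not passing. Stress, time of day or feeding at the time of sampling may differ between the genotypes in the same way, and this was not tested.

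B cell genes were lower while Igj was higher. A candidate explanation is that the SHP-KO pieces held no lymphoid follicle. Follicle and high endothelial genes outside the fixed lists, not looked at before, had a median log2 fold change of -2.64, below all 10000 matched random lists. Of 16 tested, 13 were lower (Ccr7 and Madcam1 among them), Bcl6 and Chst4 were higher and Tnfrsf11b did not pass. Whether follicles were left out in dissection or are fewer without SHP cannot be read from these libraries. Muscle, nerve and fat markers rose by list medians of 2.14 or more, as more outer wall and mesentery in the SHP-KO pieces would give, but dissection and genotype cannot be told apart because every library of a genotype shows it.

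Proximal markers were higher and ileal markers lower in SHP-KO. A smaller share of ileum as the whole cause is argued against by 6 ileum markers that were higher by more than 2 SE, while Fabp6 fell 74.7-fold. Slc10a2 was among the 6, at 2.20-fold higher. The limit of 2 SE is a low bar here, as 70.6% of all tested genes were called. Pyy, another of the 6, also stands in the enteroendocrine list, of which 16 of 18 markers rose, so its rise says little about the segments. A larger share of jejunum as part of the cause stays open: 11 of 12 proximal markers were higher, which is the pattern itself, and the labels give no share of either segment, so it cannot be told apart from an effect of SHP loss.

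The scatter of cholesterol synthesis genes between SHP-KO libraries is unusual because other genes scarcely differ there. A difference in depth or quality acting on genes of any function is argued against: the list's median ratio of highest to lowest library, 1.23, exceeded 100% of 10000 matched random lists, whose highest median was 1.12. A sterol response that moves the whole pathway together in some mice is argued against by a mean pairwise correlation of 0.082 among 24 members over the 3 libraries, with Mvd highest in replicate 3, Pmvk in replicate 1 and Hsd17b7 in replicate 2. Errors in single table entries that fall on genes of any function are argued against: of 16 genes of at least 20 CPM that differed at least 1.5-fold, 11 were among the 22 list members at that level (Fisher's exact test, two-sided, p 6.2e-25). Of 48 genes that differed beyond counting noise after Holm adjustment, 16 were list members, against 1 of 86 in WT. Errors in the table entries of this list's genes stay open, with 5 of the 16 genes outside the list, because the reads that could decide it were not used here. Separate responses of single list genes in single mice were not tested. Chi-square per degree of freedom within a genotype was taken for genes of the immediate early, interferon, clock and B cell lists. Its median was 0.97 in WT and 0.84 in SHP-KO, against 0.98 in each for all genes with at least 50 counts. Counting noise alone gives a median below 1 here, so values near 1 do not mean that no further spread was left. Repeat libraries of one RNA or one pool per genotype cannot be told apart from separate mice, because such a comparison with counting noise does not decide it.

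The 6 libraries form 10 splits into 3 and 3, too few for a share under 0.05. The split by genotype called 8543 genes and the highest other split 0, at an adjusted p of 0.05 in edgeR. For lists the split by genotype called 17 and the highest other split 13, and 1 of the 10 splits reached the value of the split by genotype for genes and for lists. Every other split mixes the genotypes in both of its groups, so the genotype difference enters the spread and few gene calls were to be foreseen. Such splits also hold the genotypes unevenly, so their list calls are no chance level either, and no conclusion is drawn from them.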
